A study of Rattus norvegicus with 3 samples.

How the data were processed

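Total RNA of rat platelets was measured on 3 arrays, 1 each for control, sorafenib-loaded and lenvatinib-loaded platelets. Per the labels' protocols, 3 mL of blood was drawn from each of 5 F344 rats, 1 mL platelet suspensions were prepared for each group, and those of the 5 rats were pooled within a group, which reads as the same rats for all groups. Platelets were isolated by a spin at 200 g for 7 minutes. The drug was then added at 10 µg for 30 minutes at 37 °C and washed out with a spin at 1000 g for 5 minutes. The labels used here do not say whether control platelets were incubated and washed alike, so a difference from control can hold the effect of handling as well as that of the drug. RNA was extracted with a column kit and labelled with biotin and phycoerythrin, per the labels' protocols. No pair of arrays shares a group, and no p-value, standard error or false discovery rate was computed.

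The authors deposited a matrix of log2 signals with 23188 features. How background correction, summary of probes and normalization were done is not given in the sources used here. The deposited log2 values ran from 2.24 to a shared ceiling of 19.93, the 3 arrays had nearly equal quartiles, and many features had exactly the same value on several arrays, which a summary by median polish would give. A tie therefore does not show that a transcript was the same, and a value at the ceiling is only a bound. At the ceiling were 31 features in the control array, 32 in the sorafenib array and 28 in the lenvatinib array. The series value table, also log2, held 24834 features, of which 1646 more were controls, and equalled the deposited matrix within 0.00005 on all shared features. The name of the array is not given in the labels used here.

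Gene names came from the platform annotation paired with the features. One gene symbol was given for 15049 features, several for 0 and none for 8139, and features without a symbol were left out of the genes and counted apart. All 15049 gene IDs were found in a RefSeq gene table of assembly GRCr8, which changed 0 symbols and was used for names alone. No genome build is named for the array, so no coordinates are given. Where a gene had several features, that with the highest mean over the arrays was kept, which left 15037 genes. Genes were kept for the counts when their mean over the 3 arrays lay at or above the median of all genes, 4.25, which left 7519. This filter uses no group. The 1153 negative control features gave a measure of background: their 95th percentile was 7.69, and 13.0% of genes had a mean at or above it.

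Differences are log2 values of 1 array minus those of another. A gene counted as 2-fold apart at an absolute difference of 1. The spread of differences above the filter was 0.27, 0.28 and 0.25 (SD over genes, for sorafenib minus control, lenvatinib minus control and sorafenib minus lenvatinib). Each of 23 gene lists, fixed before the data were examined, was described by the median difference of its measured members and by that median's percentile among 10000 random lists of the same size drawn from genes of like mean signal, in 50 bins. A list is said to stand apart in the lowest or highest 2.5% of random lists, a description of these arrays that carries no test of the condition. List members without a named feature were not analysed here. To show what sharing an array gives when the 3 arrays are alike, each gene's 3 values were exchanged among the arrays at random in 100 draws. Exchange keeps the differences within each gene, real ones included, so that it tells whether an array stands apart from the others and gives no count of genes expected by chance.

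The genes named in the text follow a rule fixed before the data were examined: above the filter, the 10 highest and 10 lowest for each drug against control, 5 and 5 between the drugs, and 5 and 5 for a shift shared by both drugs, passing over names that are only locus numbers or predicted models. From each list, up to 4 members with the largest differences were open to naming, with every target kinase above the filter and any member of a background list. Genes at the ceiling and genes of the added lists were named after their values were seen.

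Alternatives fixed before the data were examined were no filter and a filter at the 75th percentile of genes, median centring, quantile and cyclic loess normalization of the deposited values, the mean of all features of a gene, the series value table, 1.5-fold and 3-fold thresholds, other shared references, Spearman's rho, members above the filter, random lists not matched on signal, and the mean in place of the median. Chosen after seeing the data were a filter at the negative controls' 95th percentile and lists without genes at the ceiling or without tied genes.

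The steps were tested on simulated arrays made from the 15037 genes by exchange. For sorafenib minus control, 98% of genes raised by 1.5 log2 units and 100% of those raised by 2 were recovered as 2-fold apart, against 72% of genes lowered by 1.5 and 70% of those lowered by 2. The filter on mean signal removes lowered genes of low signal: 70% of genes lowered by 2 stayed above it. Counts of lower genes are therefore understated against counts of higher genes. For lenvatinib minus control, a list of 30 genes raised by 0.3 lay at percentile 100 and an unchanged list at 49.9. For sorafenib minus lenvatinib, 6% of 200 unchanged lists were said to stand apart, where 5% is the expected share. Values were exchanged gene by gene, so these lists hold no variation shared between genes, as real lists can. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for quantile and cyclic loess normalization.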

Results

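The study measured messenger RNA in rat blood platelets, the small anucleate cells that megakaryocytes of the bone marrow release and that carry RNA from their parent cell. Platelets of F344 rats, an inbred strain, were loaded with a drug outside the body. The series title sets this in the treatment of liver cancer with a patient's own platelets as the carrier. Total RNA was hybridised to 3 arrays, 1 for control platelets, 1 for platelets loaded with sorafenib and 1 for platelets loaded with lenvatinib. Each array held RNA pooled from 5 rats, so there are no replicates, and every difference below is between single arrays with no p-value and no error. The number of arrays limits the precision. Each loading used 10 µg of drug for 30 minutes at 37 °C. Sorafenib and lenvatinib are inhibitors of several kinases, among them receptors for vascular growth factors. Values are log2 signals of 15037 named genes, of which 7519 lay at or above the low-signal filter of 4.25. The median over all features was 4.21 in the control array and 4.22 in each drug array. Differences are log2 signal of the first array named minus that of the second, and a difference of 1 is 2-fold.

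All 3 arrays carried strong platelet signal. Pf4, the chemokine platelet factor 4, Clec1b, the receptor for podoplanin, and Nrgn, neurogranin, were saturated at the ceiling of 19.93 on all 3 arrays, so that no difference between arrays can be read for them. Of 33 measured platelet surface and granule genes, 11 were higher, 8 lower and 14 tied in the sorafenib array against control, and 11, 13 and 9 in the lenvatinib array. Their median difference was 0 in both, with percentiles of 45.7 and 53.1 among random lists matched on signal, and no member was 2-fold apart. The median signal of the list was 17.56 in control. Of 244 genes at mean signals from 16 up, 0 were 2-fold apart in any comparison, so the list does not show that platelet transcripts were unchanged. The member furthest from control was Stxbp2, a protein of granule secretion, at 10.69 in control, 11.45 with sorafenib and 11.27 with lenvatinib. Alox12, the platelet lipoxygenase, read 17.56, 17.76 and 17.89. The 13 measured megakaryocyte transcription factors had medians 0.02 and 0.08 above control, at percentiles of 87.6 and 94.3. Among them Gata1, a regulator of megakaryocyte and red-cell genes, read 9.78, 9.86 and 10.03, and Runx1 read 11.65, 11.98 and 11.84. The 26 genes of the actin and adhesion machinery, with a median signal of 17.25 in control and so under the same limit, had a median difference of 0 for both drugs. Actn1, an actin cross-linker, read 11.94, 11.47 and 11.78, and Myl12b, a myosin light chain, read 10.59, 11.07 and 11.07. Genes of 2 sets from other tissues did not stand apart in any comparison: their medians were 0 for 19 liver genes and for 18 genes of brain, retina and muscle. In both sets 0 genes had a signal at or above the negative controls' 95th percentile, so these medians come from low signals.

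Platelets loaded with sorafenib were compared with control platelets to find which transcripts differ after loading. The genes furthest above control were Pak3, a p21-activated kinase, by 1.74, Lactb2, a mitochondrial ribonuclease, by 1.59, the olfactory receptor gene Or13d1 by 1.54 and Tbp, the TATA-binding protein, by 1.45. Snrpd1 and Snrpa1, proteins of the splicing machinery, were each higher by 1.36. Polr3b, a subunit of RNA polymerase III, was higher by 1.24, C17h7orf25 by 1.18, Irak3, a brake on Toll-like receptor signalling, by 1.17, and Hagh, a glyoxalase, by 1.16. The gene furthest below control was Ly96, the partner of Toll-like receptor 4 in sensing endotoxin, with a difference of -1.37. It was followed by Acbd7 at -1.32, the translation factor Eif1a at -1.31, the olfactory receptor gene Or1e1c at -1.26 and Ei24 at -1.22. The histone chaperone Nasp was at -1.17, Zfp800 at -1.15, Gmps, an enzyme of guanine nucleotide synthesis, at -1.14, the cell-cycle kinase Cdk6 at -1.11 and Ttc39c at -1.10. In all, 23 genes were at least 2-fold higher and 21 at least 2-fold lower, 0.585% of the genes above the filter. Without the filter 32 genes were higher and 45 lower. With 1 array per group no count expected by chance can be given. Of the 44 genes, 3 had a mean signal at or above the 95th percentile of the negative control features, 7.69, and Ly96 was the sole 1 of the 20 named genes to do so. Negative control features were 2-fold apart in 17.6% of cases, but the SD of their differences was 0.82, against 0.27 for genes above the filter. It was 0.28 for genes at mean signals from 4.25 to 5.67. Negative control features thus varied more than genes of low signal, and their share is no measure of how many genes differ through noise.

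Among the gene lists, 3 stood apart in this comparison. Apoptosis genes were lower with sorafenib: 10 of 17 were lower, 5 higher and 2 tied, with a median of -0.17 at percentile 0.08. Of these genes 3 had a signal at or above the negative controls' 95th percentile, and of those Mcl1 was lower and Bcl2l1 and Xiap higher. Bcl2, which restrains cell death, read 6.39 in control, 5.85 with sorafenib and 6.03 with lenvatinib. Bak1, which promotes cell death, read 5.75, 5.31 and 5.06. Bcl2l1, the main survival protein of platelets, was higher, at 16.30 in control, 16.60 with sorafenib and 16.48 with lenvatinib. With lenvatinib the apoptosis list had 7 genes higher, 6 lower and 4 tied, and a median of 0 at percentile 50.2. The sorafenib call was lost when the mean replaced the median, at percentile 6.79. Neutrophil genes had a median 0.08 above control at percentile 98.9, with 10 of 18 higher and 5 lower, but 1 member had a signal at or above the negative controls' 95th percentile. That member, S100a9, was lower, at 8.37 in control and 7.97 with sorafenib. T cell genes had a median of -0.05 at percentile 2.39, with 9 of 17 lower, 4 higher and no member at or above that level. The neutrophil and T cell calls were both lost over the members above the low-signal filter.

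Lenvatinib-loaded platelets were set against control platelets for the same purpose. Inpp1, an inositol phosphatase, was higher by 1.52, as was Lactb2. Hagh read 5.57 in control and 7.07 with lenvatinib, and Tbp was higher by 1.36 and the olfactory receptor gene Or7g12 by 1.32. Mix23 was higher by 1.25, Lgals5, a galectin of rat red cells, by 1.23, Sgce by 1.21, the lysosomal membrane protein Tmem192 by 1.19 and Ankrd27, a regulator of vesicle traffic, by 1.18. The lowest were Psmc3ip, a recombination cofactor, at -1.49, the translation initiation factor Eif2s1 at -1.48, Gpr107 at -1.45 and the nuclear envelope protein Nemp1 at -1.32. They were followed by Ccdc90b at -1.19, the centrosomal protein Cdk5rap2 at -1.17, Txnl1, a thioredoxin-like protein, at -1.16, Lypd8l1 at -1.15, the olfactory receptor gene Or10ab4 at -1.12 and the traffic factor Trappc2 at -1.09. There were 29 genes at least 2-fold higher and 20 at least 2-fold lower, or 0.652% of the genes above the filter. Of these 49 genes, 12 had a signal at or above the negative controls' 95th percentile, including Lgals5, Tmem192, Ankrd27, Txnl1 and Trappc2 among the 20 named. At mean signals from 12 to 16, 4 genes were 2-fold higher with lenvatinib and 0 lower, while no gene in that range was 2-fold apart with sorafenib. Negative control features were 2-fold apart in 16.2% of cases, with an SD of differences of 0.84 against 0.28 for genes above the filter, so the same limit holds.

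Ribosomal protein genes were lower in the lenvatinib array. Of 51 measured, 33 were lower, 10 higher and 8 tied, with a median of -0.15 at percentile 0.01, and 49 had a signal at or above the negative controls' 95th percentile. Rpl27 read 10.11 in control and 9.08 with lenvatinib, the only member of that list 2-fold apart. Rpl24 read 9.33 and 8.62, Rps25 read 12.31 and 11.66, and Rplp2 read 14.24 and 13.62. With sorafenib 22 members were higher and 22 lower, and the median was 0. Many ribosomal protein genes have near-identical copies in the genome that an array feature may also detect, so single values are uncertain.

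Erythroid genes were the background list furthest above control with lenvatinib. Of 16 measured, 11 were higher, 2 lower and 3 tied, with a median of 0.09 and a mean of 0.25, and a percentile of 97.4, just inside the central 95% of random lists. Epb42, a protein of the red-cell membrane skeleton, read 4.11 in control, 4.23 with sorafenib and 5.23 with lenvatinib. Ahsp, the alpha-globin chaperone, read 4.75, 5.03 and 5.68, and Slc4a1, the anion exchanger of red cells, read 7.93, 8.23 and 8.78. Slc25a37, a mitochondrial iron importer, read 4.49, 4.49 and 4.84. Epb42, Ahsp and Slc25a37 lay below the negative controls' 95th percentile, and of the 11 members at or above it, 8 were higher, 1 lower and 2 tied. The globin gene Hbb read 18.63, 18.56 and 18.68, Hbb-b1 read 14.00, 13.90 and 14.21, and Hba-a1 was saturated on all 3 arrays. Alpha globin genes have near-identical copies, as do beta globin genes, so their values are uncertain as well.

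**Figure D1:**
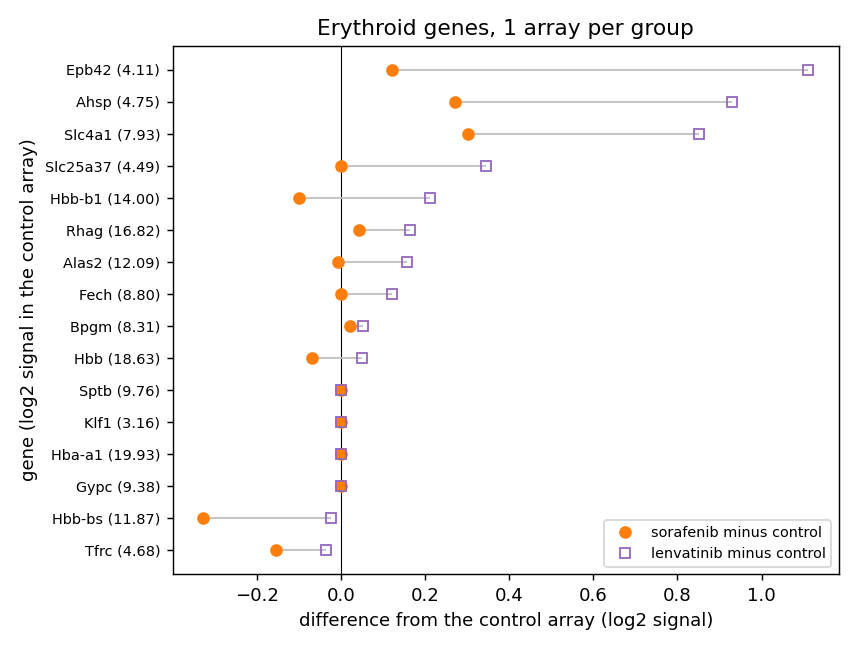
Differences of 16 erythroid genes from the control array in log2 signal, circles for the sorafenib array and squares for the lenvatinib array, with each gene's control signal in brackets. Lenvatinib was higher by 0.85 for Slc4a1, and by 0.93 and 1.11 for Ahsp and Epb42, whose signals lay below the negative controls' 95th percentile of 7.69, and Klf1, Gypc and the saturated Hba-a1 were tied on all 3 arrays.

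The lists of the drugs' own targets and of the signalling below them did not stand apart, but few of their members had a signal above background. Platelets have no nucleus and carry RNA from their parent cell, so these lists do not report whether the kinases were inhibited. At or above the negative controls' 95th percentile were 1 of 12 kinases, Kdr, 0 of 14 MAPK output genes and 1 of 15 immediate early genes, Egr1, so that the other readings given for these lists are from low signals. Of the kinases, 6 lay above the low-signal filter, and the list's percentile was 18.0 with sorafenib and 48.9 with lenvatinib. Kdr, the main receptor for vascular endothelial growth factor, read 8.98 on all 3 arrays. Araf read 6.77 in control, 6.54 with sorafenib and 6.83 with lenvatinib, Pdgfra read 5.25, 5.07 and 5.29, Kit read 5.02, 5.02 and 4.88, and Ret read 4.89 on all 3 arrays. Flt4 read 4.30, 4.84 and 5.30, just under 2-fold with lenvatinib. MAPK output genes had medians 0.01 and 0.03 above control, at percentiles of 89.3 and 93.8. With sorafenib 7 of the 14 were higher, 5 lower and 2 tied, and with lenvatinib 7, 2 and 5. Dusp6, a phosphatase that ERK signalling induces, read 4.50, 5.41 and 5.43, and Dusp5 read 4.81, 4.23 and 4.81. Immediate early genes had medians 0.02 above control with sorafenib and 0 with lenvatinib, and Egr1 read 9.16, 9.79 and 9.59. Heat shock genes had a median of 0 with sorafenib and -0.01 with lenvatinib, where their mean, 0.03, has the opposite sign. Of 23 granule growth factors and angiogenesis modulators, 9 were higher and 9 lower with sorafenib, and 9 and 11 with lenvatinib. Tgfb1 read 16.52, 16.84 and 17.14. Hgf, hepatocyte growth factor, read 6.88 in control and 6.04 with each drug, and 7 of the 23, with Tgfb1 but without Hgf, had a mean signal at or above the negative controls' 95th percentile. Drug transport and metabolism genes had medians of 0, with Abcc1, an efflux pump, at 7.89, 8.20 and 8.63. With tied genes left out, an alternative chosen after seeing the data, that list stood apart with sorafenib, at a median of 0.23 and percentile 98.6, with 5 members higher and 4 lower. Of its 13 measured genes, 2 had a signal at or above the negative controls' 95th percentile, Abcc1, which was higher, and Abcc4, which was lower. Antioxidant genes had medians of 0, with Prdx1, whose mean lay below the negative controls' 95th percentile, at 7.26, 7.08 and 6.44. Nuclear respiratory chain genes had a median of 0 with sorafenib and of -0.03 at percentile 3.22 with lenvatinib, where 15 of 27 were lower and 6 higher. With sorafenib 13 were lower, 6 higher and 8 tied, and the list stood apart at percentile 1.68 with the mean, -0.10, in place of the median, and at 0.425 with tied genes left out. Uqcrb, of respiratory complex III, read 9.94, 9.70 and 9.29. Among the lists for other blood and vessel cells, monocyte, B cell, natural killer and endothelial genes did not stand apart in any comparison. The B cell median of -0.01 in both drug arrays has the opposite sign to the mean, 0.05 with sorafenib and 0.01 with lenvatinib, and Cd74, whose mean lay below the negative controls' 95th percentile, read 7.04, 7.97 and 7.95.

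**Figure D2:**
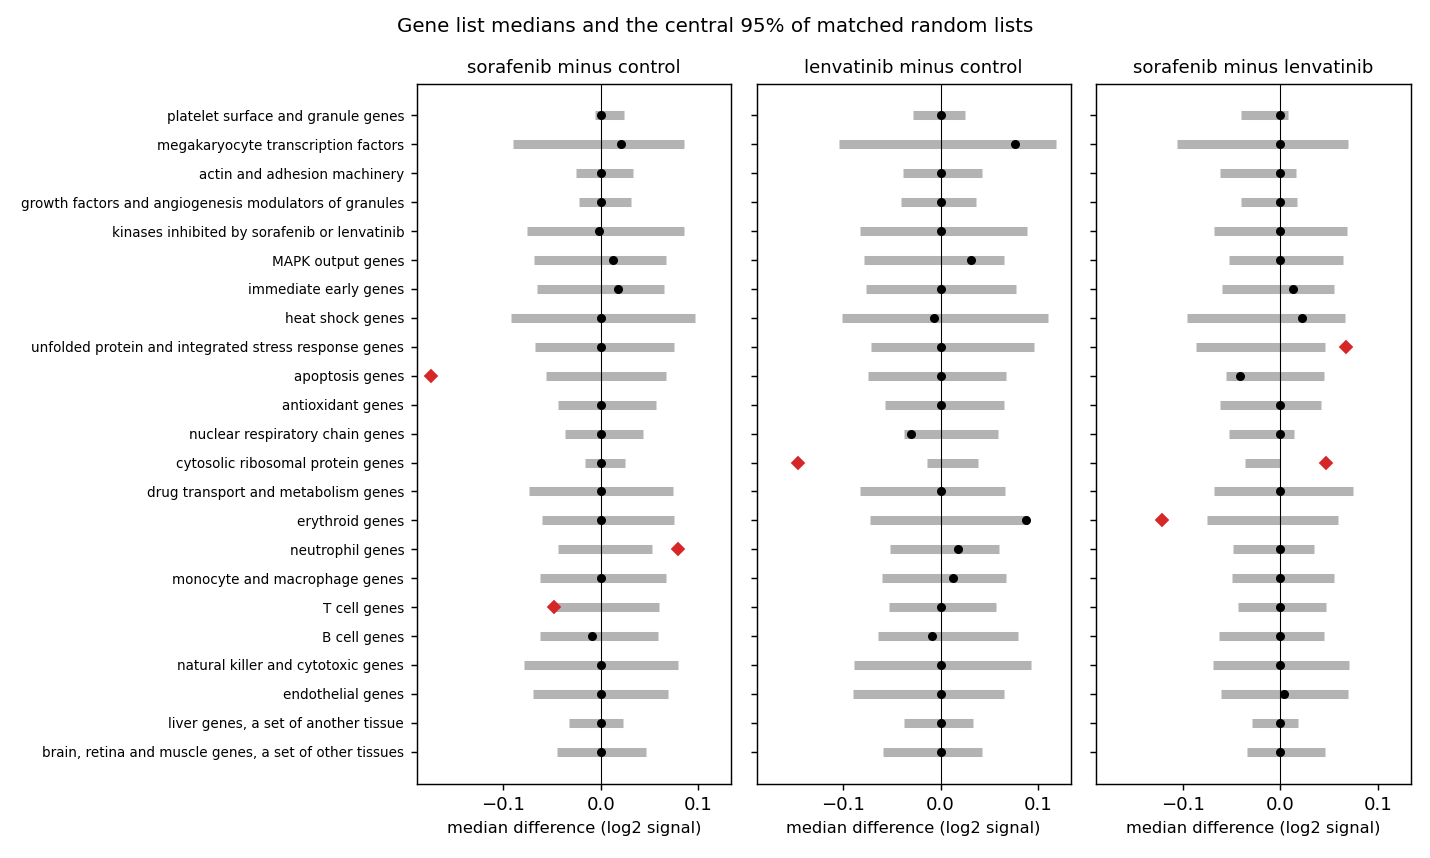
Median log2 difference of each of 23 gene lists in the 3 comparisons (points), with the central 95% of 10000 random lists of the same size matched on signal (grey bars). Diamonds mark the 7 medians among the lowest or highest 2.5%, such as ribosomal protein genes at -0.15 in lenvatinib minus control.

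The arrays of the 2 drugs were also compared with each other, at the same mass of drug and the same time. Mix23 was the gene furthest apart, at 4.21 with sorafenib and 6.37 with lenvatinib. Il18r1, a receptor chain for interleukin 18, was lower with sorafenib at -1.37, as were Letm2 at -1.30, Inpp1 at -1.27 and Or1e1c at -1.15. Thoc7, of a complex that couples transcription to RNA export, was higher with sorafenib by 1.56, Mphosph6 by 1.37, Gpr107 by 1.13, Eif2s1 by 1.12 and Sgo2, a protector of chromosome cohesion, by 1.09. In total 12 genes were at least 2-fold higher and 17 at least 2-fold lower with sorafenib, 0.386% of the genes above the filter, and none of these 10 named genes reached the negative controls' 95th percentile. Erythroid genes stood apart, with 0 higher, 13 lower and 3 tied of 16 and a median of -0.12 at percentile 0.58. Ribosomal protein genes stood apart the other way, with 31 higher, 15 lower and 5 tied of 51 and a median of 0.05 at percentile 99.9. Unfolded protein and integrated stress response genes had a median of 0.07 at percentile 98.5, with 8 of 15 higher with sorafenib and 1 lower. Atf4, the transcription factor of the integrated stress response, read 15.61 with sorafenib and 15.18 with lenvatinib, and 15.29 in control. Asns, asparagine synthetase, read 9.29 and 9.13, against 8.83 in control. That call was lost over the members above the low-signal filter. Cat, catalase, was 2-fold apart, at 11.14 with sorafenib and 12.19 with lenvatinib. Over the 3 comparisons 7 of 69 list medians stood apart, where 3.45 would do so if genes varied independently. Genes of a list can vary together, and sorafenib minus lenvatinib is the difference of the other 2 comparisons. The number 3.45 is therefore no count expected by chance.

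The differences of both drug arrays from control were then set against each other, across genes, which are not independent replicates. Lactb2, Tbp, Hagh, Or13d1 and Or11g2 were the genes furthest above control in both drug arrays, and Or11g2 was higher by 1.01 in each. Or10ab4, Gmps, Zfp870, Ttc39c and Ndrg2 were furthest below, Ndrg2 at -1.01 in each. Both drug arrays shared 7 genes at least 2-fold higher, with 0.089 expected of independent lists, and 5 at least 2-fold lower, with 0.056 expected. The same control array enters both differences, and exchanged arrays shared 4.82 higher genes on average, with a range of 1 to 11, and 4.47 lower genes, with a range of 1 to 9. Over the 7519 genes Pearson's r was 0.579, above the 0.466 to 0.524 of exchanged arrays, and the covariance was 0.044 against 0.036. Of genes that differed from control in both, 77.8% had the same sign, against 73.9% after exchange. With the sorafenib array as the shared reference r was 0.417, and with the lenvatinib array 0.499. The control array thus stood slightly further from the drug arrays than these did from each other. The control array cannot be split, so part of the overlap can come from its own chance values. Part can also come from handling, since the labels used here do not say whether control platelets were incubated and washed alike. None of the 10 genes named here reached the negative controls' 95th percentile.

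**Figure D3:**
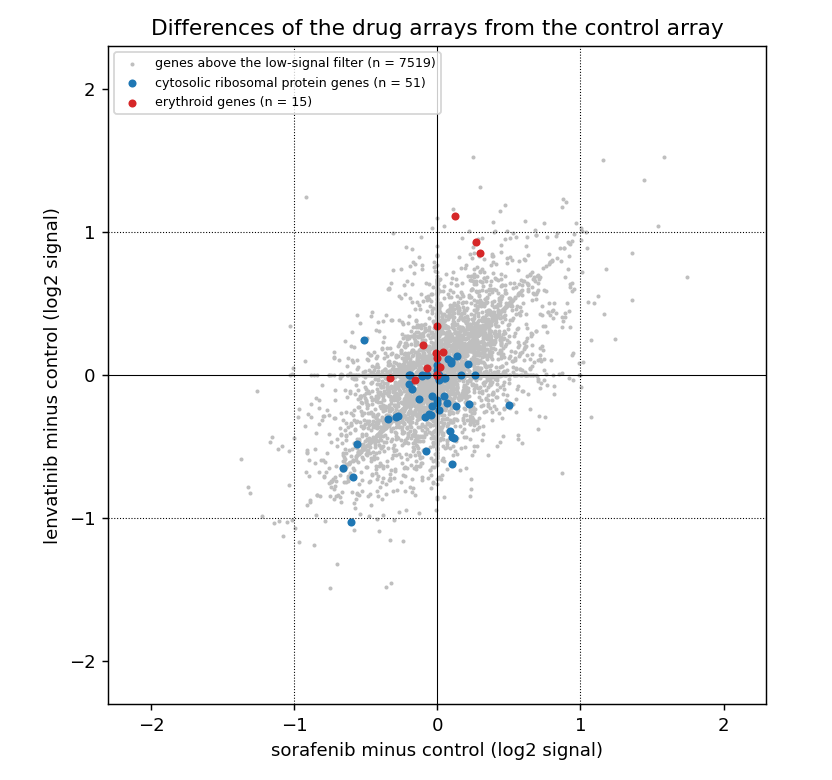
Log2 differences from the control array for 7519 genes (grey), sorafenib on the horizontal and lenvatinib on the vertical axis, with ribosomal protein genes in blue and erythroid genes in red. Dotted lines mark 2-fold. The cloud follows r = 0.579, and most ribosomal protein genes lie below 0 on the vertical axis.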

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

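Features without a gene symbol were left out of the comparisons of named genes, yet some differed from the control array. Of 3821 such features above the low-signal filter, 13 were at least 2-fold higher and 14 at least 2-fold lower with sorafenib, and 14 were higher and 13 lower with lenvatinib. These are 0.707% of the unnamed features in both cases, against 0.585% and 0.652% of the named genes.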

How the results depend on the processing

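The filter at the negative controls' 95th percentile and the lists without ceiling or tied genes were chosen after seeing the data. No paired analysis was possible because each group is 1 array. The counts of 2-fold genes stayed within 1.5 times under median centring, quantile normalization, cyclic loess, the mean of features and the series value table, the last of which equals the deposited matrix and so tests nothing. The largest shift that cyclic loess gave a gene above the filter was 0.012 in sorafenib minus lenvatinib and 0.0102 in lenvatinib minus control, so that it too says little. Of the 44, 49 and 29 genes 2-fold apart in sorafenib minus control, lenvatinib minus control and sorafenib minus lenvatinib, 41, 46 and 29 remained so under median centring. The counts depend on filter and threshold by construction, through the genes that enter or the size asked. In the same order of comparisons, without a filter 32, 42 and 17 genes were 2-fold higher and 45, 39 and 28 lower. With the filter at the 75th percentile 10, 18 and 7 genes were higher and 7, 9 and 7 lower. At 1.5-fold 204, 259 and 169 were higher and 193, 214 and 177 lower, and at 3-fold 2, 0 and 0 higher and 0, 0 and 1 lower. With the filter at the negative controls' 95th percentile, which 1961 genes passed, 2, 8 and 2 were higher and 1, 4 and 2 lower. Most of the genes counted thus lay below that level, as do most of the 7519 genes above the low-signal filter. The correlation of the 2 drug differences, 0.579, stayed between 0.572 and 0.596 under 8 alternatives, among them median centring, which cannot change it. Spearman's rho was 0.537, for which the cause was not tested, and r was 0.417 with the sorafenib array and 0.499 with the lenvatinib array as the reference, which set other arrays against each other. The 7 list medians with a call had 70 values under alternatives, of which 57 kept the call, 13 lost it and 0 changed sign, and of the 620 values of the 62 medians without a call 14 gained one. Both calls of ribosomal protein genes and that of erythroid genes between the drugs held under all 10 alternatives, with percentiles of at most 0.01, of at least 99.9 and of at most 2.28. The apoptosis call was lost under 1, those of stress response and neutrophil genes under 3 each and that of T cell genes under 6. Erythroid genes in lenvatinib minus control stood apart under 8 of 10, including the series value table at percentile 97.8, whose equal values differ only by the random lists drawn, so that this median lies at the border. The other calls gained were of respiratory chain genes under 3 settings, with sorafenib (percentiles 1.68 and 0.425) and with lenvatinib (2.2 against unmatched lists), of drug transport genes with sorafenib (98.6), and between the drugs of granule factors with the mean (2.37) and T cell genes above the filter (1.36). None of 978 differences of named genes and list members crossed 2-fold or turned sign past it under 5 alternatives. Most of these could change little. Median centring shifted no comparison by more than 0.0071, and the mean of features differs only through 12 extra features. With the series value table and cyclic loess, they say little about the calls that were kept.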

Other observations

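The test of leukocyte genes and the list without Fau and Rack1 were chosen after the results had been seen. Cyclic loess was set beforehand as a test of signal-dependent differences between the arrays. It moved no gene above the filter by more than 0.012 in sorafenib minus lenvatinib or 0.0102 in lenvatinib minus control. A smooth trend with signal was thus small in the deposited values. The 2 gene lists below were written after the patterns they address had been seen, but before their medians were computed, although the values of Eef1a1 had been seen. None of their genes is on a list fixed earlier. Of 19 measured genes of a second translation list, 12 were higher and 4 lower with sorafenib than with lenvatinib, with a median of 0.11 at percentile 99.8. That list holds Fau, which encodes a ribosomal protein, and Rack1, which is part of the small ribosomal subunit, and the 17 genes without them lay at percentile 99.7. It also holds Hnrnpa1, Nap1l1 and Npm1, which are not parts of the translation machinery, and was not tested without these. Btf3, a nascent-chain binding factor, read 15.43 with sorafenib and 14.93 with lenvatinib, and the initiation factor subunit Eif3l, 1 of the 2 members below the negative controls' 95th percentile, read 5.51 and 4.90. Of 32 measured further red-cell genes, 15 were higher, 4 lower and 13 tied with lenvatinib against control, with a median of 0 and a mean of 0.08. Rhd, a red-cell surface antigen with a signal below the negative controls' 95th percentile, read 6.41 in control, 6.03 with sorafenib and 6.79 with lenvatinib.

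Erythroid genes were lower in the sorafenib array than in the lenvatinib array, with a median of -0.12. Random lists matched on signal ranged from -0.08 to 0.06 (central 95%). After cyclic loess the erythroid median was still -0.12, and no member had moved by more than 0.011. These values argue against a smooth signal-dependent difference as the source for this list. More red-cell RNA in the lenvatinib pool may account for the pattern, but the further red-cell genes, with 16 lower and 8 higher, lay at percentile 4.98, outside the lowest 2.5% and on the same side, which leaves it open. Of these 32 genes 5 had a signal at or above the negative controls' 95th percentile. In sorafenib minus lenvatinib, Hemgn (0.27), Bnip3l (0.03) and Isca1 (0.003) were higher, and Mkrn1 (-0.14) and Tent5c (-0.12) were lower. The most abundant erythroid genes, Hba-a1 and Hbb, are at or near the ceiling, where a small share of red cells would not show. The first spin, at 200 g, would leave most red cells behind, and 11 of the 16 erythroid genes had a signal at or above the negative controls' 95th percentile. Whether this signal came from platelets, whose parent cells share precursors with red cells, or from remaining red cells was not tested. A biological effect of the drugs on platelet RNA was not tested apart from the amount of red-cell RNA, as group and pool are the same.

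Ribosomal protein genes were lower in the lenvatinib array than in the control array, with a median of -0.15. The central 95% of random lists matched on signal ran from -0.01 to 0.04. After cyclic loess the ribosomal protein median was -0.14, and no member had moved by more than 0.0053. These values argue against a smooth signal-dependent difference as the source for this list. Less leukocyte RNA in the lenvatinib pool could lower such genes, but 50 genes of the 5 leukocyte lists lay at percentile 96.0 with 25 higher and 13 lower and a median of 0.002, which decides nothing. Of these 50 genes 8 had a signal at or above the negative controls' 95th percentile, and Ccl5 among them is also on the granule list. The second translation list lay at percentile 7.29, with 12 of 19 lower, and at 8.46 without Fau and Rack1. A shift shared with the genes of that list, not all of them of the translation machinery, stays open. Near-identical gene copies, differences of handling and an effect of the drug were not tested.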
